A study of Caulobacter vibrioides with 6 samples.

How the data were processed

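The data were RNA sequencing libraries of 6 pull-downs from Caulobacter crescentus, 3 with DNA oligonucleotides antisense to AbnZ and 3 with scrambled oligonucleotides. Per the labels' protocols, cells were crosslinked with UV light and broken with glass beads, RNA was extracted from streptavidin beads and treated with DNase, and libraries were made with a directional Illumina kit from NEB. The groups were taken from the words Plus and Minus in the sample titles, which the design text of the series ties to antisense and scrambled oligonucleotides. The titles of the antisense samples name an empty vector and their genotype field the AbnZ plasmid, and the latter was followed because the design text names it too. The words Plus and Minus stand directly after vanillate in the titles and descriptions, and can be read as with and without vanillate, but the treatment field gives vanillate for all 6 samples and the design text ties the words to the oligonucleotides, so these were followed.

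The authors deposited TPM values (read density per gene scaled to a fixed total per library) for 4085 genes in each of the 6 libraries, with rRNA included, and each column sums to 1000000, per the file headers and values. The aligner, the counting tool, the strand setting, the genome build and the annotation are not given in the sources used here. Without the strand setting, reads of overlapping and antisense genes cannot be told apart, and copies of the rRNA and tRNA genes share reads, so both were summed as classes. They also stayed in the gene test as single genes, where copies that share reads are not independent.

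Gene symbols, lengths and neighbours came from a RefSeq gene table of assembly ASM2200v1, in which 4068 of the 4085 names were matched and 17 were not. No coordinates are printed, because the build of the deposited table is not given. The product of TPM and gene length was a whole multiple of 1 step per library for 21569 of 21569 values above 0, within 0.01 read, and that step was taken as 1 read. This gave total reads of 4541263 to 8687493 per library. The reads were used for depth, for shares of RNA classes, for floors of 3 reads and for alternatives, and reads of unmatched genes are not known. Because TPM divides by the whole sum, a change in a few abundant RNAs moves every other value, and with under 5% of reads outside rRNA in each library the median protein-coding gene had 9 to 15 reads. Counting error is therefore large for most genes.

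The main test was limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with trended and robust empirical Bayes variances, over genes with at least 1 TPM in at least 3 libraries. A Benjamini-Hochberg adjusted p under 0.05 counted as passing. The plan written before the data were examined gave a count model first and this test for a table of normalised values, and the table holds TPM. A fold on the log2(TPM + 1) scale understates the change of low genes. Genes were named by a rule set before the data were examined. It took the bait, its operon and hfq, the 10 genes with the largest change in each direction among those that passed and whose groups did not overlap, leaving out rRNA and tRNA genes, which were reported as classes, and up to 4 members with the largest change in each list described. Exceptions are marked where they occur.

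The 15 gene lists were tested with camera at a preset correlation of 0.01, with an estimated correlation and with fry, adjusted over the 15 lists. Product names are absent from the tables used here, so lists of ribosomal proteins, flagellum and chemotaxis, respiration and sigma factors were drawn from gene symbols, and lists of TonB-dependent receptors, efflux proteins by product and the TAM complex were not formed. Shares of RNA classes were compared with exact two-sided permutation tests in Python 3.11.15 with scipy 1.17.1. Ratios with 1 to 3 reads in a group have exact 95% binomial counting intervals.

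The fit was tested on simulated data, with reads drawn for the real genes at the real library sizes and 200 genes changed, 50 at each fold. Of 50 genes changed 2-fold, 11 were called in the right direction, against 41 at 4-fold, 45 at 8-fold and 44 at 16-fold, over 3343 simulated genes of antisense against scrambled libraries. In that run 10 of 151 calls were of unchanged genes, and a run without changes gave 0 calls. The simulated spread was a single value for both groups, averaged from the median spread of the better-covered genes in each. No library stood apart in the simulation. In the data, libraries correlated at 0.779 to 0.844 within the scrambled and 0.882 to 0.915 within the antisense group. Changes in genes that vary more are found less often, so these recoveries may be too high for the real data.

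The alternatives were 4 other scalings, no filter, a filter of 50 reads in 3 libraries, limma-voom on the recovered reads, a test against a log2 change of 1, pseudocounts of 0.1 and 5, a replicate block, and each library left out in turn. Added after the data were seen were median-ratio scaling for camera, the 4 other scalings for fry, and shares of tRNA, small RNAs and housekeeping RNAs without the gene with most reads. Among the other scalings, the one without rRNA, tRNA and CCNA_R0123 left out a locus taken as the candidate bait after its values were seen.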

Results

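RNA from pull-downs aimed at the bacterial small RNA AbnZ was measured in Caulobacter crescentus strain NA1000 (CB15N), a freshwater bacterium with an asymmetric cell cycle. Per the labels, the cells lacked vanA and vanB, carried Hfq with a 3xFLAG tag, Hfq being the RNA chaperone of many small RNAs, and held a plasmid expressing AbnZ from a vanillate-induced promoter. The treatment fields of all 6 libraries and the design text give induction for 15 min with 500 µM vanillate at an optical density of 0.4, followed by UV crosslinking. Streptavidin beads then captured RNA with DNA oligonucleotides antisense to AbnZ in 3 libraries or with scrambled oligonucleotides in 3 libraries. The titles of the 3 antisense libraries name an empty-vector plasmid, whereas their genotype field and the design text of the series name the AbnZ plasmid. The titles and descriptions also place the words Plus (antisense) and Minus (scrambled) directly after vanillate, and can be read as libraries with and without vanillate. The treatment fields and the design text were followed here, and a difference in vanillate or plasmid between the groups cannot be ruled out from the labels. The libraries held 6903793, 5451459 and 4541263 reads with scrambled oligonucleotides and 8348086, 8384487 and 8687493 reads with antisense oligonucleotides. Outside rRNA, 159170, 235251 and 119175 reads remained in scrambled replicates 1, 2 and 3 and 233928, 193681 and 291773 in antisense replicates 1, 2 and 3. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these libraries, which may be technical.

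The first comparison was of the bait itself. As background, AbnZ is understood to come from the 3′ end of the mRNA of an acrAB-nodT efflux pump. The table does not name AbnZ, and the locus fixed beforehand as AbnZ, CCNA_R0149, held 1 read over the 6 libraries and was not tested. CCNA_R0123, an ncRNA of 108 nt beside CCNA_00849 at the end of the acrB2 operon, was taken as the candidate bait locus after its values were seen. It averaged 114280 ± 45411 TPM with antisense oligonucleotides (SD, n = 3) and 55831 ± 74767 TPM with scrambled oligonucleotides (SD, n = 3). In antisense replicates 1, 2 and 3 it took 26.3%, 19.5% and 33.9% of the reads outside rRNA. In scrambled replicates 1 and 3 it took 2.86% and 2.83%, but in scrambled replicate 2 it took 21.6%, within the range of the antisense libraries. The fitted log2 change of CCNA_R0123 was 1.93 (SE 0.86) and did not pass the limma test (adjusted p = 0.205). Without scrambled replicate 2 it was 3.10 (SE 0.30, adjusted p = 0.0034), and under the other alternatives the adjusted p of CCNA_R0123 ranged from 0.1003 to 0.9999.

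Of the pump operon genes, 1 of 3 passed the test. CCNA_00849, the gene next to CCNA_R0123, fell from 1096 ± 625 to 191 ± 12.1 TPM (SD, n = 3 each), a log2 change of -2.35 (SE 0.44, adjusted p = 0.0301). The call of CCNA_00849 was lost in 7 of 17 alternatives, among them median-ratio scaling (adjusted p = 0.0655), scaling to total reads (0.0548), the fit without scrambled replicate 3 (0.0854) and the fits without antisense replicate 1, 2 or 3 (0.110, 0.116 and 0.125), over a range of 0.0141 to 0.428. The pump gene acrB2 averaged 55.4 ± 23.1 TPM with scrambled and 20.53 ± 3.68 TPM with antisense oligonucleotides, with a log2 change of -1.31 that did not pass (adjusted p = 0.0771). It passed in 2 alternatives and did not in 15. CCNA_00851 was at 9.99 ± 0.81 and 7.94 ± 1.02 TPM and did not pass (log2 change -0.30, adjusted p = 0.508), and its log2 change was above 0 under 3 of 4 other scalings, at 0.097, 0.12 and 0.22. The tagged hfq gene was at 62.3 ± 30.1 and 53.2 ± 5.84 TPM (log2 change -0.13, adjusted p = 0.850). As a list, the 3 operon genes did not pass the camera test (adjusted p = 0.0730), and among the alternatives they passed only without scrambled replicate 1 (adjusted p = 0.0248). Genes named tamA or tamB were not analysed here, since neither the table nor the reference used here carries those symbols.

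**Figure D1:**
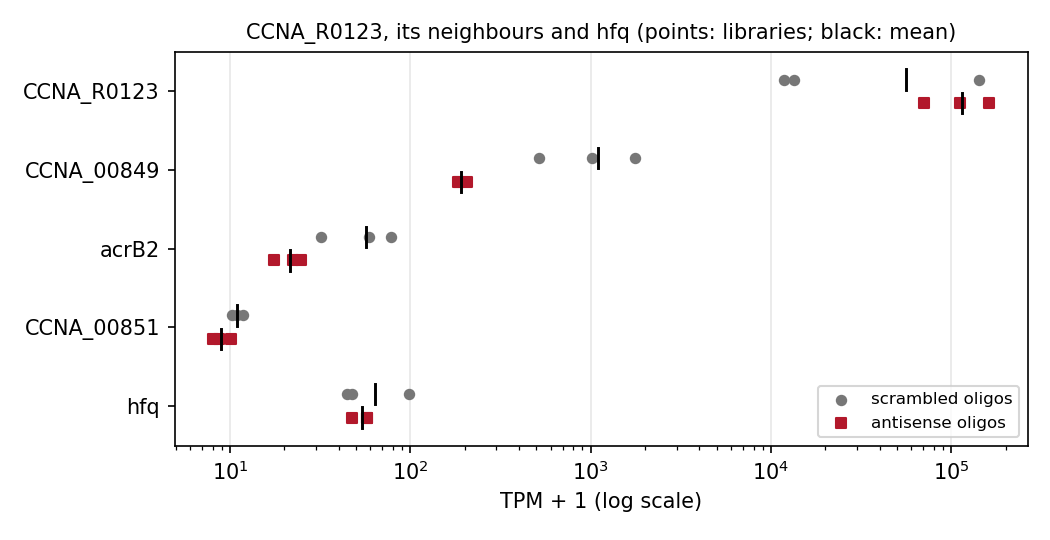
TPM + 1 on a log axis for CCNA_R0123, the genes CCNA_00849, acrB2 and CCNA_00851 beside it, and hfq. Grey circles are the 3 scrambled libraries, red squares the 3 antisense libraries and black lines the group means. One scrambled library holds CCNA_R0123 at the antisense level, while CCNA_00849 averages 1096 TPM with scrambled and 191 TPM with antisense oligonucleotides.

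The comparison of antisense with scrambled pull-downs over all genes asked which RNAs differed between them. Since the candidate bait locus did not pass, a gene called here cannot be read as captured along with AbnZ. On the log2(TPM + 1) scale, the largest changes among genes that passed were lower levels with antisense oligonucleotides. The gene mopB fell from 422 ± 320 to 0.774 ± 0.686 TPM (SD, n = 3 each), from 3046 reads to 9 reads per group, with a log2 change of -7.72 (SE 0.56, adjusted p = 0.0013). The gene ccrM, which encodes the DNA adenine methyltransferase of the cell cycle, fell from 1035 ± 763 to 5.14 ± 1.68 TPM, or 10256 against 86 reads (log2 change -7.14, SE 0.55, adjusted p = 0.0013). CCNA_03169 had the highest level of the 10 genes outside rRNA and tRNA that fell most, at 3804 ± 1810 TPM, and fell to 90.4 ± 24.0 TPM (log2 change -5.31, SE 0.40). The gene pleC, encoding a sensor histidine kinase that also sets cell polarity, fell from 143 ± 106 to 4.57 ± 0.61 TPM, and lnt, encoding the apolipoprotein N-acyltransferase, from 165 ± 112 to 5.26 ± 0.07 TPM. CCNA_02151, CCNA_00765 and CCNA_03989 had log2 changes of -5.48, -4.91 and -4.49. The ncRNA CCNA_R0077 fell from 1121 ± 467 to 50.8 ± 21.0 TPM. The ncRNA CCNA_R0014 had 55 reads with scrambled and 2 with antisense oligonucleotides, a ratio per total reads of 41.4 with a 95% counting interval of 10.9 to 350.2. Of those 55 reads 46 came from scrambled replicate 2, and without it the ratio was 9.99 (95% counting interval 2.07 to 95.1). The call of CCNA_R0014 was lost in 11 of 16 alternatives (adjusted p 0.0175 to 0.268). In mopB, ccrM and pleC the scrambled SD was large because scrambled replicate 2 had the highest values, yet each of the 3 scrambled libraries lay above each antisense library. Without scrambled replicate 2 the scrambled mean was 239.7 TPM for mopB, 618 for ccrM, 85.4 for pleC, 105 for lnt, 204 for CCNA_02151, 42.6 for CCNA_00765 and 68.2 for CCNA_03989, where all 3 libraries gave 450, 92.3 and 104 TPM for the last 3. The calls of mopB, ccrM, CCNA_03169, CCNA_03989, lnt and CCNA_R0077 held in each of the 17 alternatives, and that of pleC was lost without antisense replicate 3 (adjusted p = 0.0513, over a range of 0.0029 to 0.0513). Those of CCNA_02151 and CCNA_00765 were lost in 5 of 17 and 4 of 16 alternatives (adjusted p up to 0.0586 and 0.0878).

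Among genes that rose and passed the test, CCNA_00312 had the largest change on the log2(TPM + 1) scale and rose from 11.3 ± 9.03 to 82.1 ± 3.56 TPM (SD, n = 3 each; log2 change 3.02, SE 0.50, adjusted p = 0.0221). The toxin gene vapC rose from 2.12 ± 1.06 to 18.1 ± 3.27 TPM (log2 change 2.65, SE 0.33, adjusted p = 0.0099). CCNA_03182 rose from 5.26 ± 2.60 to 34.2 ± 5.73 TPM and CCNA_03818 from 3.34 ± 1.57 to 22.3 ± 5.91 TPM. CCNA_03922 rose from 4.31 ± 1.91 to 22.2 ± 2.79 TPM. CCNA_02436 and CCNA_03082 had log2 changes of 2.58 and 2.31, from 8 reads each in the scrambled group. CCNA_01510 had 2 reads with scrambled and 68 with antisense oligonucleotides, a ratio per total reads of 22.6 with a 95% counting interval of 6.02 to 190. CCNA_03015 had no read with scrambled oligonucleotides and 24 with antisense, and was at least 1.49-fold higher against a floor of 3 reads per library. CCNA_03829 had 0 and 10 reads, under the floor, so no fold is given. The calls of these 10 genes held under the 4 other scalings, and each was lost in 2 to 5 of the 6 fits that left out a library. The 4 scalings all shifted log2 changes upward, to a median over all genes of -0.20 to 0.11 against -0.34 as deposited. Holding under them is therefore a weak check on a rise. The small RNA CCNA_R0118 had a larger log2 change, 3.63 (SE 1.03), from 7.50 ± 9.87 to 67.2 ± 43.2 TPM and 8 reads against 123, but did not pass (adjusted p = 0.0758). It passed in 2 alternatives, without scrambled replicate 2 (adjusted p = 0.0180) and with rRNA, tRNA and CCNA_R0123 left out of the total (0.0329), over a range up to 0.617. The scrambled mean of CCNA_R0118 was 1.91 TPM without scrambled replicate 2, that of CCNA_00312 was 6.22 TPM without scrambled replicate 3, and those of CCNA_02436 and CCNA_03082 went from 1.68 and 1.13 to 0.335 and 0.573 TPM without scrambled replicate 1. The scrambled mean of CCNA_01510 was 0.636 TPM and 0.393 without scrambled replicate 3, and the antisense mean of CCNA_03829 was 4.62 TPM and 2.64 without antisense replicate 2. Counting intervals and floors cover counting error only.

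**Figure D2:**
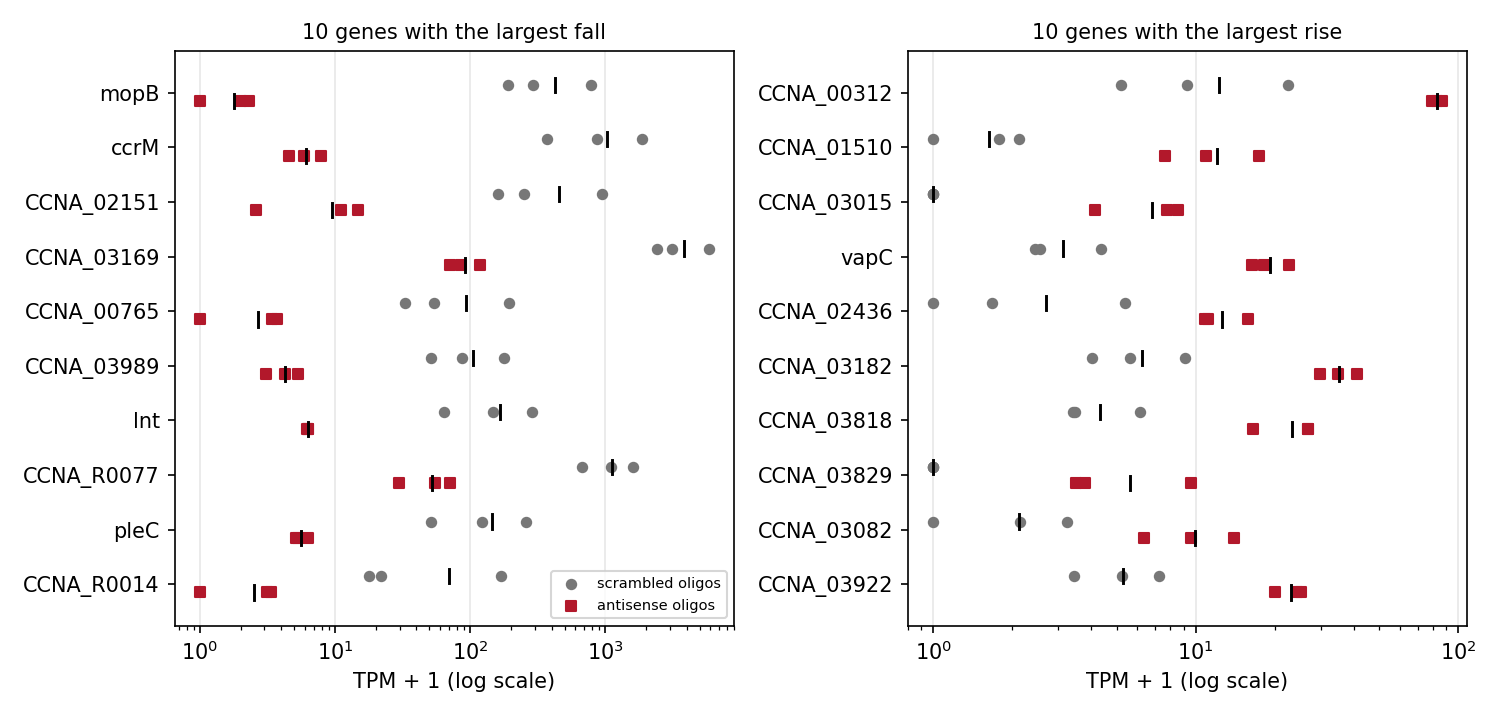
TPM + 1 on a log axis for the 10 genes with the largest fall (left) and the 10 with the largest rise (right) on the log2 scale among genes other than rRNA and tRNA that passed the test. Grey circles are the 3 scrambled libraries, red squares the 3 antisense libraries and black lines the group means. mopB goes from 422 to 0.774 TPM on the left and CCNA_00312 from 11.3 to 82.1 TPM on the right.

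Of 3342 genes tested with limma on log2(TPM + 1), 59 were higher and 128 lower with antisense oligonucleotides at an adjusted p under 0.05. Of the higher genes 57 were protein-coding and 2 were ncRNA. Of the lower genes 103 were protein-coding, 11 were tRNA, 8 were ncRNA and 4 were rRNA, with 1 antisense RNA and 1 SRP RNA. For each gene that passed, the libraries did not overlap between the groups. Over all tested genes, 256 lay wholly above and 860 wholly below in the antisense libraries, 33.4% in total against the 10% that chance gives. The median log2 change of all tested genes was -0.34, and the split between higher and lower genes moved with the scaling, from 31.6% higher on the deposited TPM to 71.1% with median-ratio scaling (108 higher, 44 lower), 69.4% with upper-quartile scaling (120 and 53), 53.5% with scaling to total reads (61 and 53) and 71.7% with rRNA, tRNA and CCNA_R0123 left out (157 and 62). Leaving out scrambled replicate 1, 2 or 3 gave 29, 135 or 18 higher and 95, 243 or 33 lower genes, and leaving out antisense replicate 1, 2 or 3 gave 0, 1 or 0 higher and 22, 16 or 11 lower genes. At an unadjusted p under 0.05, the fits without antisense replicates 1 and 3 had 145 and 143 higher genes.

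**Figure D3:**
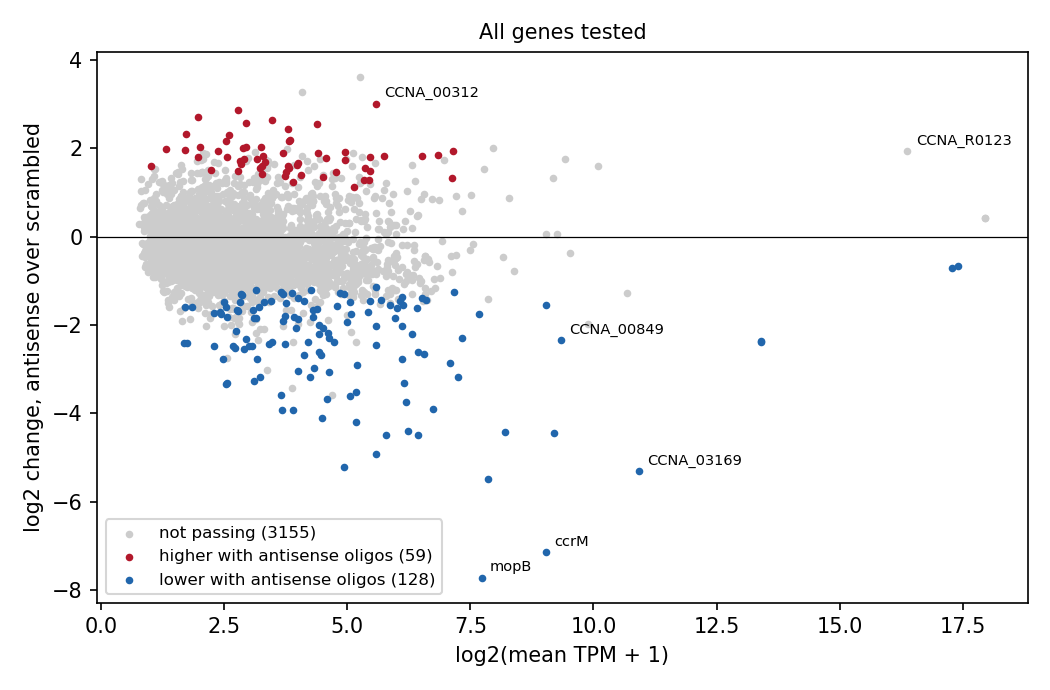
Log2 change of antisense over scrambled libraries (vertical) against log2(mean TPM + 1) over both groups (horizontal), 1 point per tested gene. Red points are the 59 genes higher and blue points the 128 genes lower at an adjusted p under 0.05, and grey points are the 3155 genes that did not pass.

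The topics of 15 gene lists were fixed before the data were examined. The members of the ribosomal protein, flagellum and chemotaxis, respiration and sigma factor lists were drawn afterwards from gene symbols, because product names were missing. The pump operon list was planned as acrA, acrB and nodT, and was tested as CCNA_00849, acrB2 and CCNA_00851. In the camera test with a preset correlation, 6 of the 15 lists were lower with antisense oligonucleotides than other genes, and none kept its call with an estimated correlation. Of 20 cell cycle regulators, 3 fell and 17 did not pass (adjusted p = 0.0271, and adjusted p = 0.235 with an estimated correlation). These were ccrM and pleC, given above, and chpT, encoding the phosphotransferase of the CtrA pathway, which fell from 16.8 ± 0.93 to 6.49 ± 0.69 TPM. The call of chpT was lost under each of the 4 other scalings (adjusted p 0.0585 to 0.215) and in 12 of 16 alternatives. Adjusted over the list alone, 8 of the regulators were lower and 1 higher, and popA, at 9.03 ± 1.91 and 20.8 ± 2.34 TPM, did not pass over all genes (adjusted p = 0.0550). The gene popA passed in 6 alternatives and did not in 11. The call of this list was lost with median-ratio scaling (adjusted p = 0.0695) and without scrambled replicate 2 (adjusted p = 0.0563), over a range of alternatives up to 0.235. Of 26 ribosomal protein genes, rpsK, rpsN and rpsC fell and 23 did not pass (adjusted p = 2.17e-04, and adjusted p = 0.473 with an estimated correlation), and 11 were lower adjusted over the list alone. The gene rpsK fell from 95.3 ± 13.6 to 31.9 ± 14.2 TPM and rpsN from 141 ± 44.5 to 51.0 ± 10.7 TPM. Under the 4 other scalings rpsK, rpsN and rpsC all lost their calls (adjusted p 0.0629 to 0.155, 0.0974 to 0.242 and 0.0792 to 0.306), and over the 17 alternatives they lost 10, 15 and 13 calls.

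Of 10 chaperone and protease genes, dnaK fell, from 25.7 ± 0.25 to 10.6 ± 0.57 TPM, and 9 did not pass (adjusted p = 0.0209, and adjusted p = 0.235 with an estimated correlation). The call of dnaK was lost under each of the 4 other scalings (adjusted p 0.0716 to 0.233) and in 11 of 17 alternatives. In this list 5 genes were lower adjusted over the list alone, and clpB stood at 12.7 ± 5.80 and 3.59 ± 0.89 TPM. Of 51 flagellum and chemotaxis genes, the flagellin gene fljL fell, from 74.6 ± 15.6 to 26.7 ± 3.84 TPM, and 50 did not pass (adjusted p = 0.0271, and adjusted p = 0.400 with an estimated correlation). The call of fljL was lost under each of the 4 other scalings (adjusted p 0.0503 to 0.197) and in 10 of 17 alternatives. None of the 51 passed adjusted over the list alone, and the list's call was lost with median-ratio scaling (adjusted p = 0.0586) and without scrambled replicate 1 (adjusted p = 0.0868), over a range of alternatives up to 0.400. Of 3 housekeeping RNAs, the signal recognition particle RNA CCNA_R0005 fell from 267 ± 76.2 to 53.0 ± 13.96 TPM, while RNase P RNA CCNA_R0061, at 2345 ± 844 and 920 ± 116 TPM, and the transfer-messenger RNA ssrA, at 423 ± 88.2 and 244 ± 39.2 TPM, did not pass over all genes (list adjusted p = 0.0209, and adjusted p = 0.235 with an estimated correlation). The call of CCNA_R0005 was lost in 4 alternatives and held in 12. All 3 housekeeping RNAs were lower adjusted over the list alone.

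The fry test asks whether the genes of a list move one way on balance, without comparing them with other genes. On the deposited TPM, where the median of all genes was itself -0.34, it passed for 11 of the 15 lists, all lower. It passed for 3 lists with median-ratio scaling, 3 with upper-quartile scaling, 7 with scaling to total reads and 1, the tRNA genes, with rRNA, tRNA and CCNA_R0123 left out. On the deposited TPM it did not pass for the ribosomal proteins (adjusted p = 0.0779), respiration (0.163), Hfq and RNA decay (0.180) or sigma factors (0.207). Among lists without a camera call it passed there for outer membrane biogenesis (adjusted p = 0.0124), cell division (0.0055), the pump operon (0.0199), rRNA (0.0017), the vanillate genes (0.0314) and small RNAs (0.0029), and none of these 6 passed with median-ratio scaling.

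The other lists did not pass the camera test. In outer membrane biogenesis, tolR fell from 9.40 ± 2.67 to 2.23 ± 0.77 TPM and 10 of 11 genes did not pass, with pal at 30.4 ± 13.9 and 9.36 ± 3.75 TPM (list adjusted p = 0.0730; 2 lower adjusted over the list alone). The call of tolR was lost in 11 of 16 alternatives, among them 3 of 4 other scalings (adjusted p 0.0432 to 0.0863). No gene passed among 26 for cell division and peptidoglycan (adjusted p = 0.243), 32 for respiration and ATP synthesis (adjusted p = 0.270), 6 sigma factors (adjusted p = 0.437) or 6 for Hfq and RNA decay (adjusted p = 0.465), where rne stood at 44.4 ± 9.24 and 22.9 ± 4.53 TPM. Adjusted over the list alone, 1 sigma factor was lower and none passed in the other 3 of these lists. Of 60 small RNAs other than CCNA_R0123, 2 rose, 9 fell and 49 did not pass (adjusted p = 0.800), and adjusted over the list alone 4 were higher and 13 lower. The ones that rose were CCNA_R0025, from 2.75 ± 1.61 to 14.1 ± 5.17 TPM, and CCNA_R0197, from 24.3 ± 4.54 to 59.9 ± 5.86 TPM, both named after their values were seen. Their calls were lost in 7 of 16 and 7 of 17 alternatives, each in 5 of the 6 fits that left out a library (adjusted p 0.0111 to 0.638 and 0.0090 to 0.9999 over all alternatives). Among those that fell were CCNA_R0077 and crfA, a small RNA of carbon starvation, which went from 204 ± 242 to 7.54 ± 3.42 TPM. Of the 251 scrambled reads of crfA 206 were in scrambled replicate 2, and without it the ratio of scrambled to antisense reads per total reads was 6.66 (95% counting interval 3.65 to 12.9). Its call was lost in 8 of 16 alternatives (adjusted p 0.0159 to 0.307). The camera direction of the small RNAs was up and their median log2 change was -0.09, and the median was above 0 under each of the 4 other scalings.

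Reads lay on vanA and vanB although the labels give both as deleted in every library, and the deleted part is not given in the sources used here. These reads go against that label unless they lie outside the deleted part, and they check nothing about the groups. The gene vanA fell from 164 ± 104 to 22.0 ± 2.99 TPM (log2 change -2.65, adjusted p = 0.0232). The call of vanA was lost in 5 of 17 alternatives, against a log2 change of 1 (adjusted p = 0.269) and without scrambled replicate 3 (0.0705) or antisense replicate 1, 2 or 3 (0.0886, 0.0864 and 0.110), over a range of 0.0084 to 0.269, and its scrambled mean was 106 TPM without scrambled replicate 2. The gene vanB was at 31.7 ± 7.29 and 13.5 ± 2.74 TPM (adjusted p = 0.0594), and the repressor gene vanR at 854 ± 466 and 614 ± 125 TPM (adjusted p = 0.634). As a list these 3 genes did not pass the camera test (adjusted p = 0.0730; 2 lower adjusted over the list alone), and among the alternatives they passed only without scrambled replicate 1 (adjusted p = 0.0248).

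Ribosomal and transfer RNA differed in composition between the pull-downs. Ribosomal RNA as a whole made up 96.9 ± 1.08% of reads with scrambled and 97.2 ± 0.52% with antisense oligonucleotides (SD, n = 3; exact two-sided permutation p = 0.9). Within it, 16S rRNA made up 34.8 ± 0.69% with scrambled and 53.3 ± 1.23% with antisense oligonucleotides, and 23S rRNA 61.9 ± 1.73% and 43.9 ± 1.09%. Reads of 16S per 23S read were 0.563 ± 0.027 and 1.22 ± 0.056. The 5S rRNA took 0.233 ± 0.049% and 0.0515 ± 0.012% of reads, and tRNA 0.0053 ± 0.0029% and 0.00075 ± 0.00016%. Small RNAs other than CCNA_R0123 took 0.0285 ± 0.0048% and 0.0134 ± 0.0014%, and housekeeping RNAs 0.0611 ± 0.013% and 0.0296 ± 0.0043%. For each of these classes the libraries of the groups did not overlap, and the exact two-sided permutation p was 0.1, the smallest that 3 against 3 libraries allow (0.143 after Benjamini-Hochberg adjustment over 10 comparisons). Without CCNA_R0077, which held 35.5% of the scrambled reads of the small RNAs, these took 0.0183 ± 0.0071% and 0.0129 ± 0.0016% and the groups overlapped (exact permutation p = 0.3). With rRNA left out of the denominator, the housekeeping RNAs overlapped between the groups (1.08% in scrambled replicate 2 and 1.33% in antisense replicate 2; exact permutation p = 0.2). Protein-coding genes took 2.63 ± 0.59% and 2.00 ± 0.18% of reads (exact permutation p = 0.2). In the gene test, 11 of 25 tRNA genes fell and 14 did not pass (list adjusted p = 7.63e-07, and adjusted p = 0.235 with an estimated correlation; 15 lower and 1 higher adjusted over the list alone). Copies that share reads are not independent, so the list p can be too small. With scrambled oligonucleotides the tRNA genes that fell averaged from 9.56 TPM (CCNA_R0001) to 557 TPM (CCNA_R0053). CCNA_R0001 and CCNA_R0027 had 0 TPM with antisense oligonucleotides, from scrambled means of 9.56 and 9.78 TPM. For CCNA_R0014, an RNA of 83 nt, the floor of 3 reads averaged 12.2 TPM in the scrambled libraries. These 2 tRNA genes therefore rest on few reads, and no fold is given. Of 6 rRNA genes 4 fell, the 23S and 5S copies, of which both 23S copies lost their calls under 3 of 4 other scalings. The rRNA list did not pass (adjusted p = 0.115; 4 lower and 2 higher adjusted over the list alone).

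**Figure D4:**
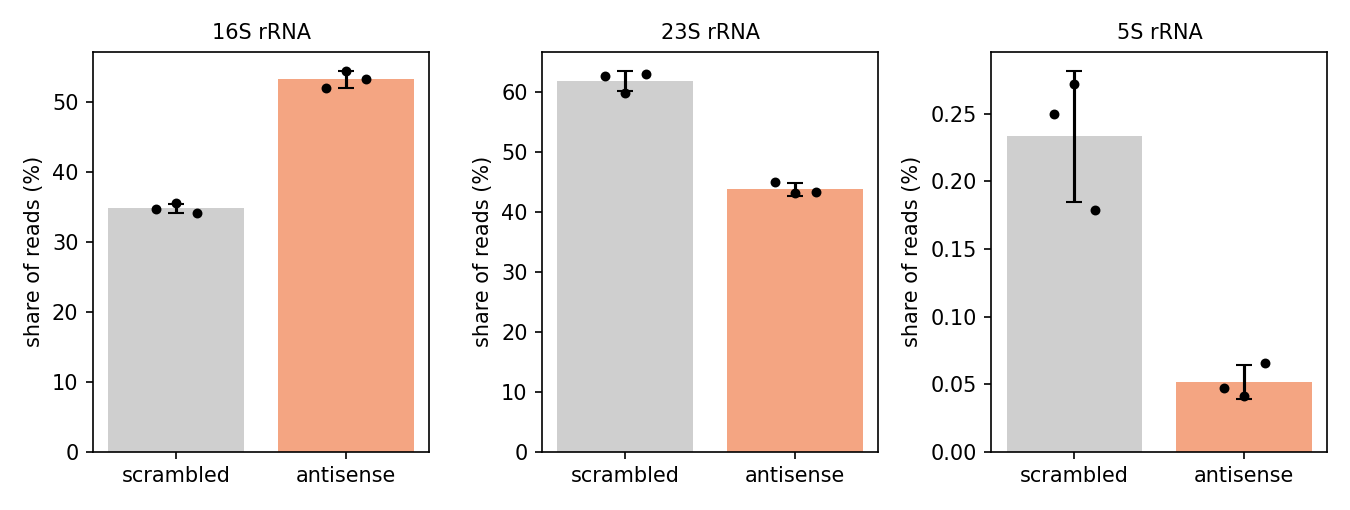
Share of all reads in percent for 16S, 23S and 5S rRNA with scrambled and antisense oligonucleotides. Bars are group means, error bars SD (n = 3) and points the libraries; 16S rises from 34.8% to 53.3% while 23S falls from 61.9% to 43.9%.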

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

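Median-ratio scaling for the gene lists, the scalings for fry and leaving out the gene with most reads of a class were chosen after the data were seen, and the other alternatives before. An exception is CCNA_R0123 in the scaling that leaves it out, since this locus was taken as the candidate bait after its values were seen. The count of higher genes was 59, and it was 108 with median-ratio scaling, 120 with upper-quartile scaling, 157 with rRNA, tRNA and CCNA_R0123 left out of the total and 0 in a limma test against a log2 change of 1 (43 at an unadjusted p under 0.05). The count of lower genes was 128, and it was 44 with median-ratio scaling, 53 with upper-quartile scaling, 53 with scaling to total reads, 62 with rRNA, tRNA and CCNA_R0123 left out, 83 with limma-voom and 12 against a log2 change of 1. All 59 higher genes were shared with the calls under median-ratio and upper-quartile scaling, as were 44 of the 44 and 53 of the 53 lower genes left there. Both scalings shift log2 changes upward, so higher genes could hardly lose their calls under them. The median log2 change of all genes was -0.34 as deposited and 0.0042 with median-ratio scaling. Leaving out 1 library gave 0 to 135 higher and 11 to 243 lower genes. The cause of these differences was not tested, apart from the scalings, which shift all genes together. CCNA_R0123 passed only without scrambled replicate 2, at 3.10, and ranged from 1.30 to 3.10 over libraries left out. No gene list kept its call with an estimated correlation (0 of 6). With fry, 11 lists passed on the deposited TPM, 3 with median-ratio scaling, 3 with upper-quartile scaling, 7 with scaling to total reads and 1 with rRNA, tRNA and CCNA_R0123 left out.

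The values did not show a pairing by replicate number: deviations of libraries with the same number correlated at 0.29, -0.08 and -0.13, and only those of number 1 correlated best with each other. Deviations within a group sum to 0, which ties these correlations together, so a shared batch or culture is not excluded. A replicate block gave 35 higher and 102 lower genes, kept the 6 lists, and changed no call of CCNA_R0123.

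With rRNA left out of the denominator, the difference between antisense and scrambled libraries became -0.142 percentage points for tRNA, -0.483 for small RNAs, 17.4 for CCNA_R0123, -1.14 for housekeeping RNAs and -15.7 for protein-coding genes, by construction of the smaller denominator. The housekeeping RNAs then overlapped between the groups, and their exact permutation p went from 0.1 to 0.2. Over all reads, leaving out CCNA_R0077 changed the difference of the small RNAs from -0.0151 to -0.00543 percentage points, and leaving out CCNA_R0061 that of the housekeeping RNAs from -0.0315 to -0.00447. Leaving out CCNA_R0053 changed that of tRNA from -0.00457 to -0.00209. These genes hold many reads of their class. Of 1078 values for 65 other named genes under alternatives, 874 stayed on their side of the threshold, 167 lost and 37 gained a call. DESeq2 was not run, since the plan gave limma for a table of normalised values. The recovered reads would have allowed it, and limma-voom was run on them. The symbols tamA and tamB gave no values. Depth limits low genes: 9 higher and 25 lower genes averaged under 10 reads.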

Other observations

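The genes in this paragraph were named after their values were seen. The gene smbA, encoding a c-di-GMP binding protein, fell from 137 ± 109 to 7.32 ± 1.14 TPM (SD, n = 3 each; adjusted p = 0.0145). The gene cdnL, encoding a CarD-like transcription regulator, fell from 239 ± 151 to 28.3 ± 5.87 TPM (adjusted p = 0.0219). The holdfast inhibitor gene hfiA fell from 85.5 ± 8.16 to 28.8 ± 4.32 TPM (adjusted p = 0.0232), while hfsB, a gene of holdfast synthesis, rose from 13.2 ± 9.29 to 46.3 ± 4.42 TPM (adjusted p = 0.0442). The response regulator gene ntrX rose from 14.1 ± 6.72 to 45.8 ± 6.24 TPM and shpA from 22.0 ± 2.60 to 63.9 ± 12.8 TPM. Of 17 alternatives, smbA lost its call in 4, cdnL in 5, hfiA in 7, hfsB in 7, ntrX in 9 and shpA in 6, each of them in all 3 fits without an antisense library. Without scrambled replicate 2 the scrambled mean was 75.6 TPM for smbA, 157 for cdnL and 815 for exbD, and without scrambled replicate 3 that of hfsB was 7.87 TPM. The surface layer gene rsaA was at 518 ± 55.9 and 536 ± 36.2 TPM (adjusted p = 0.923). Of the genes that power TonB-dependent uptake, exbD was at 1564 ± 1299 and 323 ± 33.2 TPM (adjusted p = 0.0661) and exbB at 225 ± 81.2 and 397 ± 57.2 TPM (adjusted p = 0.156), and neither passed.

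In the paragraphs below, the tests of mixing by the higher genes and of gene length were set before their values were seen; all others were chosen afterwards, and no biological explanation was tested for the level of CCNA_R0123 or for rRNA and tRNA. Over the 10 splits of the 6 libraries into 3 and 3, the real split gave 187 genes and the highest other split 0, and 1 split, the real one, gave as many. The splits are too few for a share under 0.05.

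CCNA_R0123 stood 11.2-fold higher in scrambled replicate 2 than in the other scrambled libraries. Material of the antisense libraries mixed into it is argued against by the 16S share of reads, which lay at 0.057 of the way from the other scrambled libraries to the antisense mean, whereas CCNA_R0123 lay at 1.23. For 134 genes higher without this library the median position was 0.447 (quartiles 0.085 and 0.790). It lay between the bounds set for that test and nearer the bound for mixing, so that test decided nothing. The argument against mixing thus rests on the 16S share, which was chosen afterwards. One higher capture factor for all captured RNA was examined with the 59 genes that fell by 2 or more log2 units without this library. Their 95th percentile of log2 excess in this library was 2.28, below the 3.49 of CCNA_R0123, and 44 of the 59 were above the other scrambled libraries. The 59 genes were picked as high in scrambled replicates 1 and 3, which lowers their excess in scrambled replicate 2, so the test cannot decide. The excess was not particular to CCNA_R0123. In scrambled replicate 2 crfA was at 482 TPM, against 39.2 and 90.3 in scrambled replicates 1 and 3, and CCNA_R0014 at 167 against 16.9 and 20.8. CCNA_R0077 and CCNA_R0129 went the other way, at 666 against 1097 and 1600 and at 198 against 374 and 245. Small RNAs other than CCNA_R0123 and CCNA_R0077 took 0.0265% of its reads, against 0.0141% and 0.0143%. A difference in AbnZ expression in that sample stays open and was not tested. A difference in vanillate or plasmid between the groups, which the labels leave possible, would not by itself set a single scrambled library apart from its group.

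For the lower genes, the share of rRNA, tRNA and CCNA_R0123 in the TPM total was examined as a cause. With these left out, the median log2 change of the 128 genes went from -2.16 to -1.64, with a median SE of 0.381 before and 0.384 after. Of the 128 genes 61 kept their call, which argues against this share as the whole cause for those 61. The others lost their call to a smaller change at a like spread. The median cannot decide for the 128 as a set, since they were picked as lower and this scaling shifts all genes together. With it, the median of all tested genes went from -0.34 to 0.11 and the calls to 157 higher and 62 lower. Gene length was tested for the 103 lower protein-coding genes only, and not for the tRNA, rRNA or ncRNA among the 128. Their median of 783 nt lay within the 639 to 906 nt of 10000 random lists matched on expression, which argues against length for these protein-coding genes. Of these 103 genes 27 had a lower neighbour in gene order, against a mean of 7.68 in random lists (one-sided permutation p = 0.0001, the smallest they can give). Among 57 higher genes 4 had a higher neighbour (mean 1.86, one-sided permutation p = 0.233). The random lists drew genes singly and so broke up operons. Any difference acting on whole transcripts would make neighbours fall together, so the count cannot tell capture by the scrambled oligonucleotides from other causes. Pairing of the lower RNAs with the scrambled oligonucleotides may contribute and was not tested, since no sequence was used here.

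The lower shares of tRNA and 5S rRNA in these antisense libraries have a loss of short RNA as a candidate explanation. Of 25 tRNA genes 14 did not pass, and the list lost its camera call with an estimated correlation (adjusted p = 0.235). Small RNAs of 200 nt or less had a median log2 change of -1.40 over 27 genes, against -2.47 for tRNA, and with an interquartile range of 2.13 this decides nothing. Less large ribosomal subunit on the antisense beads is argued against as the whole cause, because 5S reads per 23S read changed as well, to 0.310 of the scrambled value.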
